A study of Arabidopsis thaliana with 24 samples.

How the data were processed

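RNA from whole Arabidopsis plants was extracted with Trizol, amplified, labelled with biotin and hybridized to ATH1 arrays, 1 array per sample. Plants grew in soil in a greenhouse or growth chamber, with 8 h of light at 21 °C and 16 h of dark at 16 °C. The 24 arrays formed 8 groups of 3, Col-0, mkk1, mkk2 and mkk1/mkk2, each untreated and 24 h after BTH. Groups and replicate letters were taken from the sample titles. The samples called untreated here are titled Time 0 in Col-0 and no-treatment, with no time, in the mutants. The sample descriptions call every sample untreated Col-0, and the treatment notes give the 100 µM spray for the mkk2 and mkk1/mkk2 BTH samples and a control treatment for the other 18, Col-0 and mkk1 after BTH among them. These fields disagree with the titles and source names, on which the BTH label of the Col-0 and mkk1 samples rests. The labels do not say whether replicates came from separate plants, and the p-values therefore measure only the spread between these samples.

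The deposited values are log2 RMA expression values, which the authors made with RMA (robust multi-array average, a background correction, quantile normalization and summary per probe set). They are given to 2 decimals, and neither the RMA version nor which arrays were normalized together is stated. The deposited table held values for 22810 probe sets. The 64 AFFX control probe sets were set aside for quality measures, and the remaining 22746 were tested with no filter on level. No pair of arrays held identical values (0 pairs). No value was transformed again. A log2 change of 1 is 2-fold.

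Probe sets were named from the array annotation and a reference gene table. A single gene symbol was given for 13513 probe sets, 13436 of them also in the reference, several symbols for 503 and none for 8730. Only probe sets with 1 gene were named or counted in lists, while the counts of changed probe sets cover all 22746. A gene with several probe sets was represented by the one with the highest mean over the 24 arrays. Because many probe sets had no symbol, 61 of 505 genes in the lists first drawn up had a single-gene probe set in this annotation, and these are called measured. Of 20 genes chosen to be named in any case, MKK1 and MKK2 among them, 19 had no such probe set and were not analysed.

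Each comparison was a contrast in a linear model of the 8 group means, fitted to all 24 arrays with limma 3.58.1 (lmFit and eBayes, no trend) in R 4.3.3 with data.table (version 1.17.8). P-values were adjusted by the Benjamini-Hochberg method over the 22746 probe sets within a comparison, and an adjusted p under 0.05 was called. There were 14 comparisons, made of BTH against untreated in each of 4 genotypes, each mutant against Col-0 untreated and at 24 h, the difference of each mutant's BTH response from that of Col-0, and the departure of untreated mkk1/mkk2 from the sum of the single mutants' changes. The tests were checked on simulated data with changes of 0.5, 1 and 2 on the log2 scale in 200 probe sets per comparison. For BTH in Col-0 they found 10.45%, 70.15% and 98.48% of these, and 4 of 123 calls were false. The simulated values were independent and normal with the same spread in all groups, which is what limma assumes. The shares found check the calculation and are not the power reached on these arrays.

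Gene lists were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the 29 lists with at least 3 measured members, beside camera with an estimated correlation and fry. Camera compares a list with the other probe sets, and fry asks whether its genes move on balance one way. Of the 44 lists, 24 were fixed before the data were examined, as were the comparisons, the rule for named genes and most alternatives. The other 20, mostly gene families, were fixed after the annotation table had been seen and before any comparison was computed. Some genes are in 2 lists. Calls were also counted with p-values adjusted over the members of a list alone.

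Named genes were the 8 with the largest rise and the 8 with the largest fall in each comparison among called single-gene probe sets whose arrays did not overlap between the groups, up to 4 called members of each list with the largest change, MKK1, MKK2 and 18 other genes fixed in advance. For the 3 differences in response and the departure from the sum, overlap was not asked for. The text names part of these and gives the rest as counts.

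The size of each mutant's BTH response was the slope through the origin of its log2 changes on those of Col-0 over the probe sets called in Col-0. The range when 1 array was left out is given beside it, which shows the weight of single arrays and is not an error of the slope. Likeness between comparisons was Pearson's r across probe sets and the overlap of calls per direction. Where both comparisons used the same Col-0 arrays, 20 simulations with no changes gave the r and covariance that random spread in shared arrays produces. The untreated Col-0 arrays were also split 1 and 2 so that none was shared. Neither step removes a shift common to all untreated Col-0 arrays. The alternatives were leaving out each array, a replicate block, fitting only the groups compared, leaving out the 40% dimmest probe sets, centring arrays on their medians, quantile normalizing again, a variance prior with a trend, array weights, single-gene probe sets, a 2-fold minimum and leaving out 3 arrays that stood apart. The default array weights did not converge on these arrays, so weights estimated gene by gene were used. No main test treated replicate letters as pairs, and the replicate block was an alternative only. A check asked whether deviations from the group means correlated above 0.1 across conditions for each letter, which held for BTH in mkk1/mkk2 alone (0.17 to 0.31). Even there, BTH-treated replicate C correlated better with an untreated array of another letter. Array data carry no read depth, and signal near background limits what can be seen.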

Results

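Transcript levels were measured on 24 ATH1 arrays of Arabidopsis thaliana, 3 for each of 8 groups. The groups were Col-0, the wild-type accession, the single mutants mkk1 and mkk2, and the double mutant mkk1/mkk2, each untreated and 24 h after BTH, sprayed at 100 µM where the dose is stated. BTH (benzothiadiazole) is a synthetic compound that acts like the defence hormone salicylic acid. MKK1 and MKK2 encode MAP kinase kinases, enzymes that pass signals by phosphorylating other kinases. The comparisons asked which genes BTH changed in each genotype, which genes differed between the mutants and Col-0, and whether the response to BTH itself differed. No sample is titled as mock-sprayed, so a BTH comparison also holds whatever the spraying and the elapsed time changed. The untreated Col-0 samples are titled Time 0 and the untreated mutant samples no-treatment, with no time given. A difference in harvest time between them cannot be told apart from genotype, and it would also enter the differences in response. For Col-0 and mkk1 after BTH the treatment notes name a control treatment, so their BTH label, and with it their BTH comparisons, the comparisons with Col-0 at 24 h and each difference in response, rests on titles and source names. Array values ran from 2.27 to 14.14 on the log2 scale and array medians from 5.57 to 5.78. With 3 arrays per group, the number of arrays limits the precision. Changes are log2 differences ± the standard error from limma, with n = 3 arrays per group, and p-values are two-sided and adjusted over 22746 probe sets.

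Arrays of 1 group correlated across probe sets at r = 0.932 to 0.996, with a median of 0.990, and arrays of different groups at 0.857 to 0.994. Taken as standing apart were 3 arrays with the lowest mean r of their own groups, untreated mkk1/mkk2 replicate A (mean r 0.933), BTH-treated Col-0 replicate A (0.975) and untreated mkk2 replicate B (0.976). Untreated mkk1/mkk2 replicates B and C had 0.961 and 0.962, means that include their r with A. The next lowest of the other groups were close, BTH-treated Col-0 replicate C (0.978) and untreated mkk2 replicate C (0.981). The difference between bioC and bioD, control transcripts added to the labelled sample before hybridization, parted the genotypes. It was -1.95 to -1.53 on the 12 Col-0 and mkk1/mkk2 arrays and -3.48 to -3.06 on the 12 mkk1 and mkk2 arrays, with no overlap. No group had arrays in both sets, so for the single mutants against Col-0 the array set and the genotype cannot be told apart, and no value within 1 set can be had. The BTH and untreated arrays of each genotype lay in 1 set, as did all mkk1/mkk2 and Col-0 arrays. The 3' minus 5' difference of the GAPDH control, a sign of RNA integrity, was 0.70 to 1.18 in untreated Col-0 and 0.60 to 0.73 after BTH, 0.26 to 0.31 and -0.04 to 0.23 in mkk1, 0.30 to 0.61 and -0.07 to 0.19 in mkk2, and 0.29 to 1.27 and 0.14 to 0.52 in mkk1/mkk2. It was lower after BTH with no overlap in mkk1 and mkk2. Untreated mkk1 and mkk2 also lay below untreated Col-0 with no overlap, and each mutant after BTH, mkk1/mkk2 included, below BTH-treated Col-0. What this did to the BTH comparisons and to those between genotypes was not tested.

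**Figure D1:**
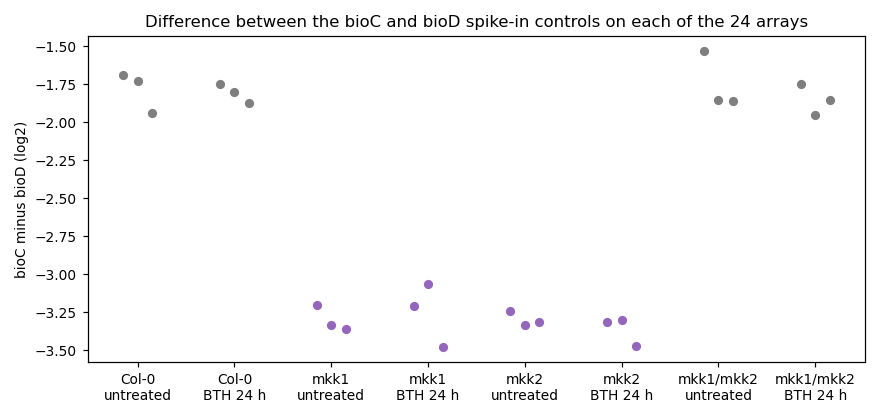
Difference between the bioC and bioD spike-in controls (log2, vertical axis) on each of the 24 arrays, by group (horizontal axis). Each dot is an array, grey for Col-0 and mkk1/mkk2 (-1.95 to -1.53) and purple for mkk1 and mkk2 (-3.48 to -3.06).

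The mutated genes MKK1 and MKK2 had no probe set assigned to 1 gene in the annotation used, so their levels were not analysed here and the genotype labels could not be checked by them. They were 2 of 20 genes that were to be named whatever their values, and 19 of the 20 had no such probe set, among them PR1, PR2, ICS1, PAD4, WRKY70 and MPK4, which were not analysed here. The 1 that was measured was PDF1.2 (AT5G44420), a plant defensin of the jasmonate and ethylene branch, at 5.76 ± 0.63 (SD, n = 3) in untreated Col-0.

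In Col-0, BTH raised defence-related and uncharacterised genes by up to 37.7-fold. AT1G13470 rose by 5.24 ± 0.34 (37.7-fold, adjusted p = 3.9e-09), AT5G55450 by 5.23 ± 0.40 and AT5G52760 by 4.76 ± 0.48. CHI (AT2G43570), a chitinase, went from 4.75 to 9.04, a change of 4.29 ± 0.28, and GRX480 (AT1G28480), a glutaredoxin, changed by 3.63 ± 0.23. Of 29 genes listed under other defence signalling, 9 rose and 1 fell, among the risers UGT76B1 (AT3G11340) (2.38 ± 0.35), a glycosyltransferase, and RING1 (AT5G10380) (1.95 ± 0.31), a ubiquitin ligase. Genes of protein folding in the endoplasmic reticulum rose with them, 8 of 17, with 9 when adjusted over the list alone. They included CRT1b (AT1G09210), a calreticulin (2.37 ± 0.42), ATERDJ3B (AT3G62600), a co-chaperone (4.58-fold, adjusted p = 0.0015), and ENGase85A (AT5G05460), which trims N-glycans (1.87 ± 0.20).

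Other genes fell after BTH in Col-0. The largest named falls were AT2G27420 at -4.36 ± 0.45 (adjusted p = 2.3e-06), AT1G62510 at -3.12 ± 0.51 and AT2G15020 at -3.03 ± 0.41. ORA47 (AT1G74930), a transcription factor of jasmonate synthesis, fell by 1.90, SWEET2 (AT3G14770), a sugar transporter, by 1.47, and the ubiquitin ligase PUB25 (AT3G19380) by 1.75, while its relative PUB24 (AT3G11840) rose by 1.48 ± 0.32. Among CYP71B cytochromes P450, CYP71B23 (AT3G26210) (3.54 ± 0.46) and CYP71B24 (AT3G26230) (1.71 ± 0.32) rose and CYP71B35 (AT3G26310) fell by 1.06. AT2G27420 and ORA47 were also lower in untreated mkk1 and mkk2 than in untreated Col-0, across the array sets, as given below. For these genes a high untreated Col-0 level from its Time 0 harvest cannot be told apart from a fall with BTH. PDF1.2 changed by -0.20 ± 0.39 (adjusted p = 0.85).

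Of the 22746 probe sets, 2006 passed the test in Col-0, 1034 higher and 972 lower after BTH, and 861 of these changed at least 2-fold. The count was 7769 with array weights, 3693 without the 3 arrays that stood apart, 1241 without untreated Col-0 replicate A, 1306 without untreated Col-0 replicate B and 3158 without untreated mkk1/mkk2 replicate A, which enters through the shared estimate of the spread. The array weights put most of the weight on replicate B in each Col-0 group. In camera with its preset correlation, 6 of 29 tested lists shifted, and fry called 3 of these 6. The protein folding list rose (adjusted p = 1.24e-09, and 0.0038 with an estimated correlation). The other defence signalling list rose at 2.69e-05 (adjusted p = 0.289 with an estimated correlation). The list of ER chaperones, which overlaps the folding list, rose at 2.69e-05 (adjusted p = 0.0565 with an estimated correlation), with 3 of 5 members past the test and 5 when adjusted over the list alone. Chloroplast-encoded photosynthesis genes were lower (adjusted p = 7.32e-05, and 0.527 with an estimated correlation), as were chloroplast-encoded polymerase and ribosome genes (0.0175, and adjusted p = 0.527 with an estimated correlation). Mitosis and histone genes were higher (0.03, and adjusted p = 0.527 with an estimated correlation) with none of 17 members past the test by limma, adjusted over all genes or over the list alone. The mean level of this list was 6.43 on BTH-treated Col-0 replicate A, an array that stood apart, and 5.92 and 5.51 on replicates B and C, and without A the adjusted p was 0.42. The mean of chloroplast-encoded photosynthesis was 11.08, 10.27 and 9.92 on untreated replicates A, B and C and 9.50, 10.06 and 9.83 after BTH. Without untreated replicate A neither chloroplast list was called (adjusted p = 0.09 and 0.15), nor was the polymerase and ribosome list without BTH-treated replicate A (0.15).

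In mkk1, BTH raised genes of the same defence list, with 8 of 29 members higher and none lower by limma. CHI rose by 3.14 ± 0.28, GRX480 by 3.03 ± 0.23, RING1 by 2.75 ± 0.31 and AT1G13470 by 5.02 ± 0.34. AT5G59670, not named for Col-0, rose by 4.19 ± 0.24 and AT1G35710 by 4.04 ± 0.40. In the protein folding list 5 of 17 members rose, with ENGase85A at 1.86 ± 0.20 and ATERDJ3B at 1.81 ± 0.41. All 3 measured genes of flavonoid synthesis fell, also when adjusted over the list alone. They were DFR (AT5G42800), an enzyme of anthocyanin synthesis (-2.43 ± 0.53), the glycosyltransferase AT4G14090 (-2.23 ± 0.39) and UGT78D2 (AT5G17050) (-1.25 ± 0.29, not called without untreated mkk1 replicate A). DFR (2.05 ± 0.53) and AT4G14090 (1.43 ± 0.39) were above Col-0 in untreated mkk1, across the array sets, while UGT78D2 was not (adjusted p = 0.678) and the list was not called there. The mean of flavonoid and phenylpropanoid synthesis was 7.61 to 8.05 there, 6.32 to 7.18 in untreated Col-0 and 5.50 to 6.18 in mkk1 after BTH. PYK10 (AT3G09260), a beta-glucosidase in the root marker list, stood at 7.94 untreated and 5.44 after BTH and did not pass the test (adjusted p = 0.103). THI2.2 (AT5G36910), a thionin, fell by 1.63, the histone gene HTB1 (AT1G07790) fell by 1.38 and PDF1.2 changed by -0.01 ± 0.39 (adjusted p = 1).

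In mkk1, 1950 probe sets passed the test, 1084 higher and 866 lower. The count was 4349 with array weights, 4158 without the 3 arrays that stood apart, 1062 without untreated mkk1 replicate A, 1273 without BTH-treated mkk1 replicate A, 897 without BTH-treated mkk1 replicate B and 3120 without untreated mkk1/mkk2 replicate A, and the 6 mkk1 arrays fitted alone gave 3747. In camera 9 lists shifted, and fry called 7 of these. The folding list rose (adjusted p = 6.92e-06, and 0.0441 with an estimated correlation), as did defence signalling (5.72e-07, and adjusted p = 0.111 with an estimated correlation). ATG8 autophagy genes (0.00236), ER chaperones (0.00903; 1 of 5 higher, 3 adjusted over the list alone) and CYP71B cytochromes P450 (0.0494) were also higher, with adjusted p = 0.297, 0.259 and 0.297 with an estimated correlation. Flavonoid synthesis (0.000456), mitosis and histones (0.000634), chlorophyll and haem synthesis (0.00525) and the chloroplast-encoded polymerase and ribosome list (0.0494) were lower. With an estimated correlation these had adjusted p = 0.111, 0.469, 0.161 and 0.751. Leaving out 1 array ended the call of CYP71B cytochromes P450 in 16 of 24 cases, that of the polymerase and ribosome list in 14 and that of the other 7 lists in none. The mean level of the mitosis and histones list was 6.15 to 6.39 on the untreated mkk1 arrays and 5.62 to 5.90 on those after BTH, against 5.59 to 5.67 in untreated Col-0.

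In mkk2, BTH gave the most called defence signalling genes of the 4 BTH comparisons, 13 of 29 higher and none lower by limma. AT5G52760 rose by 6.07 ± 0.48 (67.3-fold), AT3G01830 by 5.35 ± 0.34, CHI by 4.88 ± 0.28, RING1 by 3.17 ± 0.31 and UGT76B1 by 2.99 ± 0.35. In the folding list 10 of 17 members rose, among them ATERDJ3B (2.42 ± 0.41) and CRT1b (1.79 ± 0.42), and 4 of 5 ER chaperone genes rose, 5 when adjusted over the list alone, with the stress transcription factor BZIP60 (AT1G42990) up 2.14-fold (adjusted p = 0.0011). AT1G13650 fell by 3.15, AT1G62510 by 3.02 and PUB25 by 1.86, and PDF1.2 changed by -0.55 ± 0.39 (adjusted p = 0.5). In all, 2444 probe sets passed the test, 1410 higher and 1034 lower. The count was 5248 with array weights, 4250 without the 3 arrays that stood apart and 1600 without untreated mkk2 replicate A. In camera 3 lists shifted and did so with an estimated correlation too, defence signalling (2.78e-12, and adjusted p = 0.0234 with an estimated correlation), the folding list (6.69e-10, and 0.00387) and ER chaperones (1.26e-05, and 0.0324). None of these 3 calls was lost without any 1 array, and fry called all 3 lists.

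In mkk1/mkk2, few genes changed with BTH. Of the 1034 probe sets that rose in Col-0, 671 (64.9%) stood at or above their Col-0 BTH mean in untreated mkk1/mkk2, and of the 972 that fell, 786 (80.9%) stood at or below it. CHI stood at 11.60 untreated and 12.27 after BTH, GRX480 at 10.21 and 9.81, AT5G55450 at 12.29 and 12.34, and AT1G13470 at 8.90 and 9.32. AT2G27420, which fell in Col-0 to 4.37, stood at 3.34 untreated, while SWEET2, at 7.69 after BTH in Col-0, stood at 8.45 and ATERDJ3B, at 10.37 there, at 8.93. The largest rises were AT5G51440 (2.94 ± 0.32, 7.66-fold, adjusted p = 0.00046), AT3G02480 (2.66 ± 0.48), LEA4-5 (AT5G06760), a late embryogenesis abundant protein (2.13 ± 0.44), and Fes1A (AT3G09350), a partner of heat shock protein 70 (1.77 ± 0.34). Of 47 UDP-glycosyltransferase genes 3 rose, UGT76E12 (AT3G46660) by 1.29 ± 0.25, UGT76E11 (AT3G46670) by 1.11 ± 0.22 and UGT73C1 (AT2G36750) by 0.72 ± 0.15. These calls were fragile, with LEA4-5 lost in 21 of 33 other settings, UGT76E11 in 16, Fes1A in 6, UGT76E12 in 7 of 32, UGT73C1 in 24 of 32 and AT3G02480 in 5 of 32. PDF1.2 changed by -1.27 ± 0.39 (adjusted p = 0.25).

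Of the 22746 probe sets, 76 passed the test in mkk1/mkk2, 60 higher and 16 lower. Leaving out 1 array gave 48 without BTH-treated Col-0 replicate B, 47 without BTH-treated mkk1 replicate A, 47 without BTH-treated mkk2 replicate A and 181 without untreated mkk1/mkk2 replicate C. It gave 31, 44 and 37 without BTH-treated mkk1/mkk2 replicates A, B and C, and 68 without untreated mkk1/mkk2 replicate A. The fit without all 3 arrays that stood apart gave 115. The 6 arrays of this genotype fitted alone gave 0 by limma, with or without the replicate letter as a block, while the block left 70 in the fit of all arrays. At an unadjusted p under 0.05 the fit of all arrays gave 2770, where 1137 would be expected with no change. In camera 9 lists shifted, and none did with an estimated correlation. Fry called 1 of the 9. Higher were cold and dehydration proteins (0.0011), ABA, drought and cold genes (0.022; none of 4 past the test by limma, 1 higher when adjusted over the list alone), UDP-glycosyltransferases (0.022), the folding list (0.0319) and both chloroplast-encoded lists (0.0471 and 0.0296). With an estimated correlation these had adjusted p = 0.414, 0.414, 0.414, 0.414, 0.695 and 0.602. Lower were plant defensins and thionins (0.00197), SWEET sugar transporters (0.0296) and glutathione transferases (0.0471), with adjusted p = 0.342, 0.533 and 0.414 with an estimated correlation.

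Of these 9 list shifts in mkk1/mkk2, 2 were called without any 1 of the 24 arrays, cold and dehydration proteins (adjusted p at most 0.038) and plant defensins and thionins. The means of cold and dehydration proteins were 6.60, 6.89 and 7.39 on untreated replicates A, B and C and 7.97, 7.24 and 7.46 after BTH, so that the rise was largest in A and smallest in C. ABA, drought and cold response went from 6.43, 7.56 and 8.64 to 9.25, 7.96 and 8.64, and was not called without untreated replicate A, which stood apart (adjusted p = 0.31). Chloroplast-encoded polymerase and ribosome genes averaged 6.86 on untreated replicate A against 8.69 and 8.01 on B and C, and without A the list turned downward with no call (adjusted p = 0.43). Chloroplast-encoded photosynthesis averaged 8.72 on untreated replicate C against 9.19 and 9.17 on A and B and 9.10 to 9.18 after BTH. That list was not called without C (adjusted p = 0.68) or with the replicate block (0.064), and this is the comparison whose replicate letters passed the check for pairing. The SWEET list was lost without untreated replicate A (0.36), glutathione transferases without untreated replicate C (0.34), UDP-glycosyltransferases without untreated replicate B (0.29) and the folding list without BTH-treated replicate B (0.1).

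The response to BTH differed between mkk1/mkk2 and Col-0 by a test of the difference itself. The difference in response (mkk1/mkk2 minus Col-0) was -5.18 ± 0.57 for AT5G55450, -4.82 ± 0.48 for AT1G13470, -4.03 ± 0.33 for GRX480 (adjusted p = 4.5e-07) and -3.62 ± 0.40 for CHI. It was 4.41 ± 0.63 for AT2G27420, which fell in Col-0, 2.89 ± 0.53 for SAG29 (AT5G13170), a senescence-associated sugar transporter, and 5.66-fold upward for UGT76E11 (adjusted p = 9.6e-05). AT2G27420 already stood near background in untreated mkk1/mkk2 and had little room to fall there. In all, 531 probe sets passed, 318 lower and 213 higher in mkk1/mkk2 than in Col-0. The count was 1710 with array weights, 1083 without the 3 arrays that stood apart, 345 without BTH-treated Col-0 replicate B, 348 without BTH-treated mkk1/mkk2 replicate A, 889 without untreated mkk1/mkk2 replicate A and 258 with only the 12 arrays of both genotypes. In camera 10 lists differed and none did with an estimated correlation, the smallest of these p-values being for the folding list (5.51e-05, lower; adjusted p = 0.0891 with an estimated correlation). Of the 10, 7 were called without any 1 array, and fry called 1. The ER chaperones also had a lower response (0.00527, and adjusted p = 0.345 with an estimated correlation; none of 5 past the test by limma, 3 lower adjusted over the list alone). PDF1.2 differed by -1.07 ± 0.56 (adjusted p = 0.46).

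For the single mutants the same test gave counts that hung on the settings. No probe set passed for mkk1 by limma, with 2237 at an unadjusted p under 0.05 where 1137 would be expected. The array-weighted fit gave 1539, and leaving out 1 array gave 28 without untreated Col-0 replicate C, 3 without untreated Col-0 replicate A, 3 without untreated mkk2 replicate B and 1 each without untreated mkk2 replicate A and untreated mkk1/mkk2 replicate A. In simulated data of this size the test found 43.28% of differences of 1 and 92.42% of differences of 2 on the log2 scale. These shares assume equal spread in all groups and are not the power reached on these arrays. In camera 4 lists differed for mkk1 and none did with an estimated correlation, which were mitosis and histones (1.24e-09, lower in mkk1; adjusted p = 0.297 with an estimated correlation), glutathione transferases (0.00288, higher; 0.242), chloroplast-encoded photosynthesis (0.00839, higher; 0.778, and not called without untreated Col-0 replicate A, 0.63) and flavonoid synthesis (0.00867, lower; 0.332, with none of 3 past the test by limma and 2 lower adjusted over the list alone). For mkk2, 873 probe sets had an unadjusted p under 0.05, fewer than the 1137 expected, and 5 passed, all with a larger value in mkk2. The 1 assigned to a single gene was AT1G58420, at 2.34 ± 0.39 (adjusted p = 0.043), with responses of -0.10 in Col-0 and 2.24 in mkk2, and it lost its call in 24 of 33 other settings. The array-weighted fit gave 382 for mkk2, leaving out 1 array gave 0 to 26, and 19 of the 24 arrays moved the count by over 1.5 times. In camera 2 lists differed for mkk2, defence signalling (2.69e-05, higher in mkk2; adjusted p = 0.693 with an estimated correlation) and chloroplast-encoded photosynthesis (5.93e-05, higher; 0.974, and not called without untreated Col-0 replicate A, 0.49). Fry called 1 of the 4 lists for mkk1 and 0 of the 2 for mkk2. PDF1.2 differed by 0.19 ± 0.56 for mkk1 and -0.35 ± 0.56 for mkk2.

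Over the 2006 probe sets that BTH changed in Col-0, the slope of each mutant's changes on those of Col-0 was 0.80 for mkk1, 1.01 for mkk2 and 0.11 for mkk1/mkk2. Leaving out 1 array moved these to 0.71 to 0.86, 0.90 to 1.06 and 0.05 to 0.16. For the genes that rose in Col-0 the slopes were 0.93, 1.13 and 0.10, and for those that fell 0.48, 0.72 and 0.13. Of the 2006, 958 were called in the same direction in mkk1, 1360 in mkk2 and 11 in mkk1/mkk2, and 2 in the opposite direction in each mutant. The probe sets were chosen in Col-0, which favours large Col-0 values, and genes are not independent replicates.

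**Figure D2:**
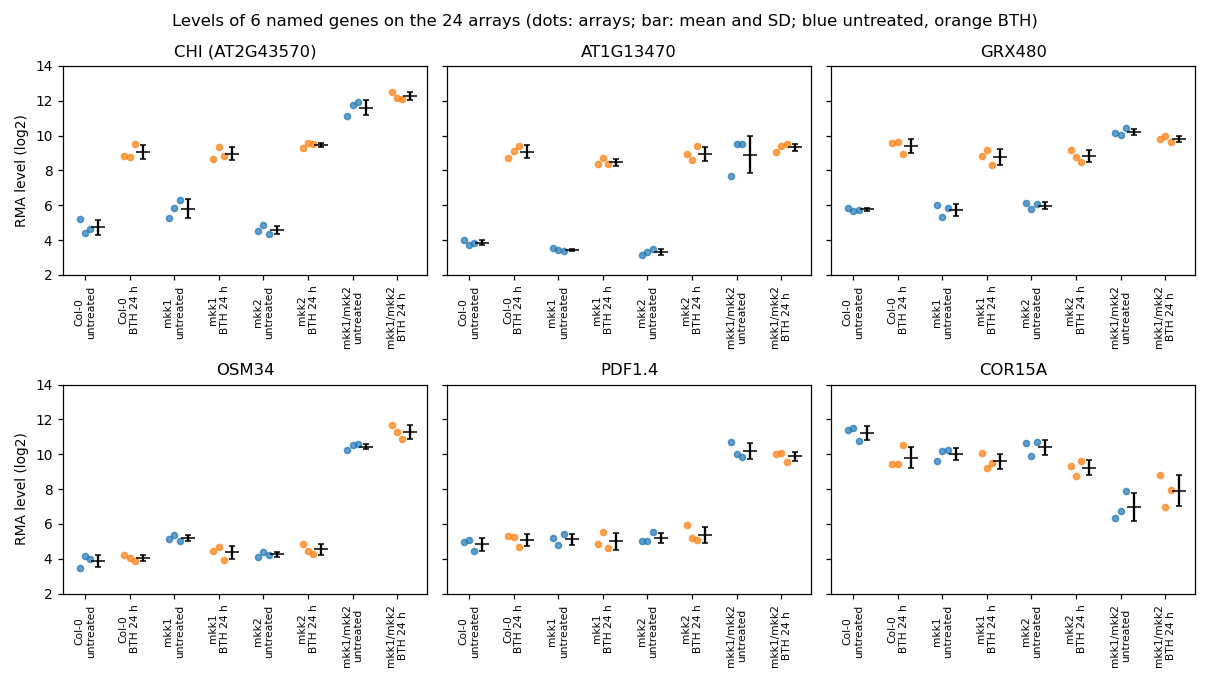
RMA levels (log2, vertical axis) of CHI, AT1G13470, GRX480, OSM34, PDF1.4 and COR15A in the 8 groups (horizontal axis). Dots are arrays (blue untreated, orange BTH) and bars the mean and SD of 3. CHI rose with BTH from 4.75 to 9.04 in Col-0 and stood at 11.60 in untreated mkk1/mkk2, while OSM34 stood at 10.44 there and at 3.88 in untreated Col-0.

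Untreated mkk1/mkk2 differed from untreated Col-0 more than BTH changed any genotype, by count. CHI was 115-fold higher (6.85 ± 0.28), OSM34 (AT4G11650), an osmotin-like defence protein, 94.6-fold (6.56 ± 0.22), MSRB9 (AT4G21850), a methionine sulfoxide reductase, 66.7-fold (6.06 ± 0.38), and GRX480 changed by 4.45 ± 0.23. OSM34 in untreated Col-0 averaged under the lower quartile of those arrays (4.02 to 4.05), so its fold rests on a level near background. Of the 29 defence signalling genes 18 were higher and 1 lower, among them UGT76B1 (3.88 ± 0.35) and the calcium sensor CML37 (AT5G42380) (3.32 ± 0.25). BIK1 (AT2G39660), a kinase of pattern-triggered immunity, was higher (2.73 ± 0.28), as was SAG101 (AT5G14930), a partner of EDS1 (1.56 ± 0.29). In the folding list 11 of 17 genes were higher, with ENGase85A at 2.14 ± 0.20 and the stress sensor BZIP28 (AT3G10800) at 1.48 ± 0.24. Of 9 ATG8 autophagy genes 5 were higher, ATG8B (AT4G04620) by 2.44 ± 0.26 and ATG8E (AT2G45170) by 1.85 ± 0.26.

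Some genes of the jasmonate branch and of auxin were higher in untreated mkk1/mkk2 and others lower. Of 15 genes of other jasmonate signalling 8 were higher and 3 lower, and the call of this list was lost without 6 of the 24 arrays in turn and without the dim probe sets (adjusted p = 0.24). PDF1.4 (AT1G19610), a plant defensin, changed by 5.36 ± 0.29, the lectin gene JAL34 (AT3G16460) by 3.21 ± 0.25, PDF1.2b (AT2G26020) by 1.38 ± 0.36 and PDF1.2 was 2.15-fold higher (adjusted p = 0.036, lost in 8 of 33 other settings), so that 5 of 7 defensins and thionins were higher, while JMT (AT1G19640), which makes methyl jasmonate, was lower (-2.68 ± 0.36). GH3.3 (AT2G23170) (5.81 ± 0.36) and WES1 (AT4G27260) (3.81 ± 0.24), which join amino acids to auxin, were higher and the auxin-responsive IAA29 (AT4G32280) was lower (-1.19 ± 0.38), the 3 measured members of the auxin list, also when adjusted over the list alone.

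Photosynthesis genes, and some genes of cold response, were lower in untreated mkk1/mkk2. Of 43 chloroplast-encoded photosynthesis genes 33 were lower and none higher by limma, with the ATP synthase genes atpA (ArthCp007) at -3.77 ± 0.92 and atpI (ArthCp010) at -3.33 ± 0.52 and ndhK (ArthCp026) at -3.18 ± 0.54. Of 19 chloroplast-encoded polymerase and ribosome genes 15 were lower, 17 adjusted over the list alone. Of 11 nuclear photosynthesis genes 7 were lower, also adjusted over the list alone, with the light-harvesting gene LHCB4.3 (AT2G40100) at -2.10 ± 0.22 and the Calvin cycle enzyme SBPASE (AT3G55800) at -1.72 ± 0.28. COR15A (AT2G42540), a cold-induced chloroplast protein, stood at 6.98 against 11.22 in Col-0 (-4.24 ± 0.44) and COR15B (AT2G42530) changed by -2.87 ± 0.40, 2 of 3 lower members among 4 in the ABA, drought and cold list (3 adjusted over the list alone). The 15 cold and dehydration proteins did not shift as a list, with 2 higher and 4 lower and a mean level of 6.96 against 7.05 in untreated Col-0. At 24 h after BTH this list was higher in mkk1/mkk2, 7.56 against 6.80 (adjusted p = 0.0433 by camera, 0.428 with an estimated correlation, 0.054 with the replicate block and 0.14 without BTH-treated mkk1/mkk2 replicate A). OSM34, far higher in mkk1/mkk2 than in Col-0 both untreated and after BTH, is a member of this list and raises both mkk1/mkk2 means. The list was not tested without it. The sugar transporter SWEET13 (AT5G50800) (-3.51 ± 0.42), the cell wall enzyme XTH32 (AT2G36870) (-3.80 ± 0.28) and 7 of 14 glutathione transferases, such as GSTU23 (AT1G78320) (-2.40 ± 0.23), were lower.

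In all, 7573 probe sets differed between untreated mkk1/mkk2 and Col-0, 3654 higher and 3919 lower, and 3878 of them by at least 2-fold. The fit of only the groups compared gave a lower count, given under processing below. There were 12 lists that shifted in camera and in fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. None held with an estimated correlation. Higher were defence signalling (2.66e-09), the folding list (6.79e-05), ATG8 (0.000713), defensins and thionins (0.0072), auxin (0.0299), ER chaperones (0.0379; 3 of 5 higher, also adjusted over the list alone) and other jasmonate signalling (0.047). With an estimated correlation their adjusted p = 0.066, 0.066, 0.206, 0.206, 0.206, 0.293 and 0.206. Lower were chloroplast-encoded photosynthesis (3.09e-09), the chloroplast-encoded polymerase and ribosome list (4.9e-05), nuclear photosynthesis (0.00331), the ABA, drought and cold list (0.0144) and glutathione transferases (0.0203), with adjusted p = 0.206, 0.311, 0.206, 0.311 and 0.206 with an estimated correlation. Without any 1 array 9 of the 12 kept their call, and lost were the ABA, drought and cold list without untreated mkk1/mkk2 replicate A (0.082), ER chaperones without any of 3 arrays and other jasmonate signalling without any of 6, each up to 0.11 without replicate B.

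The untreated mkk1/mkk2 change resembled the BTH response across probe sets. Its log2 changes correlated with those of BTH in Col-0 at r = 0.73 across probe sets, which are not independent replicates (0.68 to 0.78 when 1 array was left out). Both comparisons use the 3 untreated Col-0 arrays, and unchanged groups gave r = 0.50 in 20 simulations. Their covariance was 0.33 against a simulated 0.0258. With these arrays split 1 and 2 in the 6 possible ways, so that none was shared, r was 0.56 to 0.70 and the covariance 0.262 to 0.339. Neither the simulation nor the split removes a shift common to these 3 arrays, which would enter both comparisons. Against BTH in mkk1 and mkk2, which share no array with the untreated mkk1/mkk2 comparison, r was 0.42 (0.37 to 0.47) and 0.66 (0.61 to 0.71). Of the 1034 probe sets higher after BTH in Col-0, 897 were higher in untreated mkk1/mkk2, where 166.1 would be shared by chance between independent comparisons. Of the 972 lower, 892 were lower, where such chance gives 167.5, and 5 went the opposite way. The shared untreated Col-0 arrays raise these expected overlaps, and by how much was not simulated. Against BTH in mkk1, 821 were shared upward (174.1 by chance) and 416 downward (149.2), and against BTH in mkk2, 1100 (226.5) and 812 (178.2). The median level of the 1034 was 6.56 in untreated Col-0, 7.91 after BTH in Col-0, 8.31 in untreated mkk1/mkk2 and 8.54 after BTH there.

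Untreated mkk1 and mkk2 differed from untreated Col-0, with the 2 array sets above confounded with genotype. Of the genes that BTH raised in Col-0, GRX480 stood at 5.74 in mkk1 and 5.98 in mkk2 against 5.76 in Col-0, while others had moved. CHI was higher in mkk1 (1.06 ± 0.28, lost in 2 of 33 other settings), CRT1b was higher in mkk1 (2.13 ± 0.42) and in mkk2 (1.55 ± 0.42, lost in 5 of 33), and AT5G55450 stood at 8.86 in mkk1 against 7.11 in Col-0. CYP71B24, also raised by BTH in Col-0, was lower in both (-1.26 ± 0.32 and -1.19 ± 0.32). AT2G27420 was lower in mkk1 (-3.59 ± 0.45) and mkk2 (-3.74 ± 0.45), as were HYH (AT3G17609), a transcription factor of light signalling (-3.11 ± 0.57 and -2.87 ± 0.57), TRY (AT5G53200), a repressor of leaf hair formation (-2.87 ± 0.34 and -2.81 ± 0.34), and ORA47 (-2.22 ± 0.36 and -2.09 ± 0.36). In mkk1 the endoglucanase gene GH9B13 (AT4G02290) was higher (3.84 ± 0.87), as were PYK10 (9.85-fold, adjusted p = 0.017), GH3.3 (1.73 ± 0.36), WES1 (1.24 ± 0.24) and the mitotic kinase AUR1 (AT4G32830) (1.39 ± 0.45). The call of AUR1 was lost without any 1 of the 6 arrays compared, and that of PYK10 without untreated Col-0 replicate A or untreated mkk1 replicate A or B. In mkk2 BZIP61 (AT3G58120), a transcription factor (2.34 ± 0.37), and AKINBETA1 (AT5G21170), a subunit of the SnRK1 kinase (2.31 ± 0.40), were higher. PDF1.2 changed by -0.83 ± 0.39 in mkk1 and -0.96 ± 0.39 in mkk2 (adjusted p = 0.17 and 0.15).

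In untreated mkk1, 3931 probe sets differed from Col-0, 2151 higher (54.7%, and 41% when arrays were centred on their medians) and 1780 lower, with 7721 with array weights, 6643 without the 3 arrays that stood apart, 1745 without untreated Col-0 replicate A and 2411 without untreated mkk1 replicate A. In untreated mkk2, 1736 differed, 797 higher and 939 lower. That count was 4542 with array weights, 2810 without the 3 arrays that stood apart, 341 without untreated Col-0 replicate A, 772 without untreated Col-0 replicate B, 574 without untreated mkk2 replicate B, 3345 without untreated mkk1/mkk2 replicate A and 0 with the 6 arrays of the 2 groups alone. In mkk1, camera called glutathione transferases lower (0.00114, 6 of 14 past the test), ATG8 lower (0.00172, 6 of 9) and mitosis and histones higher (0.000373, 3 of 17, 13 adjusted over the list alone), with adjusted p = 0.165, 0.555 and 0.555 with an estimated correlation. In mkk2 it called glutathione transferases (0.0125), ATG8 (0.0125) and chloroplast-encoded polymerase and ribosome genes (0.0382) lower and the auxin list higher (0.0287; 1 of 3, 3 adjusted over the list alone). With an estimated correlation these had adjusted p = 0.464, 0.538, 0.809 and 0.468. The 3 calls in mkk1 held without any 1 array, while in mkk2 the polymerase and ribosome list was lost without untreated Col-0 replicate A (0.39) and the auxin list without untreated mkk2 replicate B (0.062). Fry called all 3 lists in mkk1 and 2 of the 4 in mkk2.

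The untreated single mutants resembled each other. Compared directly, 1 probe set differed between them when untreated and 7 did 24 h after BTH by limma, with 870 and 411 at an unadjusted p under 0.05 where 1137 would be expected. Counts below the expected number leave the sensitivity of this test in doubt, so the few calls alone do not establish likeness. Their changes against Col-0 correlated at r = 0.90 across probe sets (0.74 to 0.93 when 1 array was left out), with a covariance of 0.217, where unchanged groups sharing the Col-0 arrays gave r = 0.50 and 0.0258. With the untreated Col-0 arrays split 1 and 2 between them r was 0.65 to 0.85 and the covariance 0.156 to 0.224. Both comparisons span the 2 array sets, and neither the simulation nor the split removes a shift common to all untreated Col-0 arrays. Untreated mkk1 correlated at r = 0.64 with mkk2 24 h after BTH, each against its own Col-0 group, a pair that shares no array but spans the same sets.

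Untreated mkk1/mkk2 departed from the sum of the single mutants' changes. Of the 1034 probe sets that BTH raised in Col-0, 598 were called above the sum and 64 below, and of the 972 that fell 110 and 304, counts chosen after the values were seen. The ER chaperone and folding lists, higher after BTH in Col-0, were not called (adjusted p = 0.844 and 0.0928). AT5G52760 exceeded the sum by 7.42 ± 0.68, AT1G13470 exceeded it 63.9-fold (adjusted p = 3.9e-08), CHI by 5.96 ± 0.40 and GRX480 by 4.25 ± 0.33, as did PDF1.2, which BTH did not raise, by 2.89 ± 0.56 (adjusted p = 0.00065). All 9 ATG8 genes exceeded it, such as ATG8B (3.53 ± 0.37), as did 16 of 29 defence signalling genes, with 3 below. The chloroplast genes petG (ArthCp041) (-5.25 ± 0.70) and psaA (ArthCp022) (-4.23 ± 0.67), BZIP61 (-5.06 ± 0.52) and 7 of 11 nuclear photosynthesis genes (8 adjusted over the list alone), such as PRK (AT1G32060) of the Calvin cycle (4.59-fold, adjusted p = 0.0032), were below it. In all 6094 probe sets passed, 2797 above and 3297 below the sum. The sum holds 2 single-mutant comparisons that span the array sets, so a difference between the sets would enter it 2 times. The departure compares the untreated Col-0 and mkk1/mkk2 arrays with the untreated mkk1 and mkk2 arrays, which is how the 2 array sets part. It therefore cannot be told apart from a difference between the array sets. In camera 9 lists shifted, the lowest p-values being for defence signalling and ATG8, both above the sum (1.81e-08 and 1.81e-08), and none did with an estimated correlation (adjusted p = 0.0607 and 0.0607 with an estimated correlation). Fry called all 9.

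**Figure D3:**
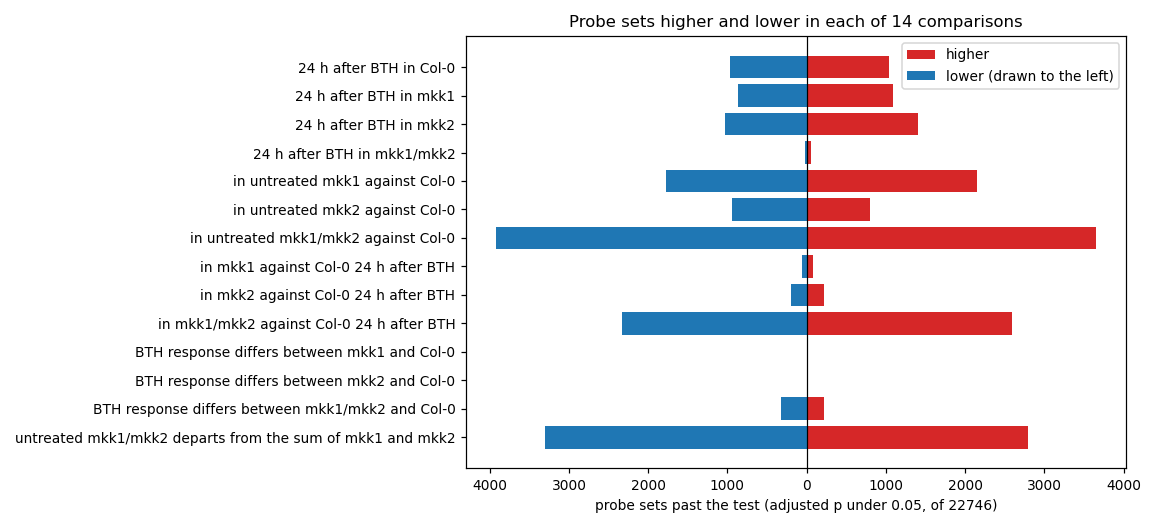
Probe sets past the test in each of the 14 comparisons (vertical axis), counted on the horizontal axis, red to the right for higher and blue to the left for lower. Untreated mkk1/mkk2 against Col-0 has 3654 higher and 3919 lower, and BTH in mkk1/mkk2 has 60 and 16.

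At 24 h after BTH, mkk1/mkk2 still differed from Col-0 in many genes. OSM34 was 147-fold higher (7.20 ± 0.22), the methyltransferase gene CCOAMT (AT1G67980) changed by 5.93 ± 0.21, GH3.3 by 5.81 ± 0.36, PDF1.4 by 4.83 ± 0.29, SAG29 by 2.52 ± 0.37 and CHI by 3.23 ± 0.28. Of the 29 defence signalling genes 14 were higher and none lower by limma, among them the protease gene SBT3.3 (AT1G32960) (8.55-fold, adjusted p = 1.1e-09) and WRKY6 (AT1G62300) (2.81 ± 0.27). MSRB5 (AT4G04830) (-3.45 ± 0.18), SWEET13 (-3.21 ± 0.42), XTH32 (-2.70 ± 0.28), LHCB4.3 (-2.06 ± 0.22) and COR15A (-1.91 ± 0.44) were lower, and PDF1.2 changed by 0.04 ± 0.39 (adjusted p = 0.97). In all 4918 probe sets passed (9417 with array weights), 2591 higher and 2327 lower, and 2052 were called higher and 1960 lower both here and in the untreated comparison, where 416.2 and 400.9 would be shared by chance. In camera and in fry 11 lists shifted and none held with an estimated correlation, the lowest being defence signalling (6.64e-10, higher; adjusted p = 0.106 with an estimated correlation). Nuclear photosynthesis was lower (0.00332; 5 of 11, 8 adjusted over the list alone; adjusted p = 0.235 with an estimated correlation) and the auxin list higher (0.00913; 2 of 3 higher and 1 lower, also adjusted over the list alone; 0.196).

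At 24 h after BTH the number of probe sets that differed between the single mutants and Col-0, again across the array sets, hung on the settings, with 141 in mkk1 and 417 in mkk2, 4111 and 5989 with array weights, and 302 and 703 without the 3 arrays that stood apart. The chloroplast gene petG was higher in mkk1 (3.26 ± 0.50) and mkk2 (2.82 ± 0.50), and AT1G04770 was lower (-2.82 ± 0.57 and -2.94 ± 0.57). In mkk2 TRY was lower (-2.02 ± 0.34), as were SWEET13 (-1.90 ± 0.42) and AT1G13650 (-2.00 ± 0.34), and BIK1 was higher (1.28 ± 0.28). Without BTH-treated Col-0 replicate A the calls of AT1G04770, SWEET13 and BIK1 in mkk2 were lost, and AT1G04770 in mkk1 lost its call in 10 of 33 other settings. PDF1.2 changed by -0.64 ± 0.39 and -1.31 ± 0.39 (adjusted p = 0.45 and 0.091). Of the 141 in mkk1, 78 were higher and 63 lower. Leaving out 1 array gave 8 (BTH-treated Col-0 replicate A) to 1215 (untreated mkk1/mkk2 replicate A), 16 of the 24 arrays moved the count by over 1.5 times, and the 6 arrays fitted alone gave 16. Of the 417 in mkk2, 217 were higher and 200 lower. That count was 70, 179 and 997 without BTH-treated Col-0 replicates A, B and C, 133, 229 and 153 without BTH-treated mkk2 replicates A, B and C, and 1470 without untreated mkk1/mkk2 replicate A. Camera called ATG8 lower in mkk1 (0.0114, and adjusted p = 0.922 with an estimated correlation) and in mkk2 (0.00579, and 0.517). In mkk2 it also called defence signalling (0.000144) and the auxin list (0.0331; none of 3 past the test by limma, 2 adjusted over the list alone) higher and glutathione transferases lower (0.0331), each with adjusted p = 0.384 with an estimated correlation. Without BTH-treated Col-0 replicate A the calls of ATG8 (0.14 in mkk1, 0.092 in mkk2), auxin (0.054) and glutathione transferases (0.075) were lost, and that of defence signalling held without any 1 array. Fry did not call the list in mkk1 and called 3 of the 4 in mkk2.

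The lists of root and pollen markers shifted in no comparison by camera (lowest adjusted p over the 14 comparisons 0.112 and 0.424), while single members changed. The 8 root and root hair markers had a median change of 0.10 in untreated mkk1/mkk2 against Col-0 and 0.03 in untreated mkk1, and the 10 pollen markers -0.12 and 0.01. Within the root list PYK10 alone passed the test in untreated mkk1 and mkk1/mkk2, at 4.64 in untreated Col-0, 7.94 in untreated mkk1 and 8.99 in untreated mkk1/mkk2. Of the pollen markers, PLIM2a (AT2G45800) was lower in untreated mkk1/mkk2, mkk1 and mkk2 (-0.97 ± 0.16, -0.74 ± 0.16 and -0.62 ± 0.16), TUA1 (AT1G64740), a tubulin, was higher in all 3 (0.92 ± 0.18, 0.81 ± 0.18 and 0.84 ± 0.18), and the tubulin gene TUB9 (AT4G20890) was lower in mkk1/mkk2 (-0.72 ± 0.18). The 4 measured reference genes changed by a median of 0.17 in untreated mkk1/mkk2, with 1 of them, AT4G34270, past the test (0.52 ± 0.11, also adjusted over the list alone). Seed storage markers had no probe set assigned to 1 gene.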

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

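The tests of the untreated mkk1/mkk2 replicate A array, of the slope (without that array, after its counts had been seen) and of the spike-in, GAPDH, root and pollen measures were chosen after the results were seen, while the regroupings of arrays and the test of genes not yet changed before treatment were planned.

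The response to BTH differed between mkk1/mkk2 and Col-0 for 531 probe sets by the test of the difference itself, and between mkk2 and Col-0 for 5. Of 100 regroupings of the 12 mkk1/mkk2 and Col-0 arrays, the real one included, 7 gave as many as 531, with up to 8382 in another. Regrouped arrays still carry the differences between genotypes and treatments, so these are not counts for unchanged responses. They cannot decide whether chance gave 531. A regrouping that calls several times the real count points to a structure of the samples, and the one with 8382 set all 6 mkk1/mkk2 arrays against all 6 Col-0 arrays, which measures the difference between the genotypes and not the response. For mkk2 13 of 100 regroupings gave at least 5, with up to 2674, and for the same reason chance cannot be judged by them there either. For mkk1 0 were called, so all 100 regroupings necessarily gave at least as many (up to 406), and this says nothing about chance. The 5 for mkk2 included AT1G58420, and the other 4 had no gene assigned.

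Few probe sets changed with BTH in mkk1/mkk2 (76), and 3 explanations were weighed. The untreated replicate A array that stood apart cannot be told apart as a source by the count, 68 without it, which leaves 2 arrays in its group, and 115 (1.51 times, past the bound of 1.5) without it and the 2 others that stood apart, but as the whole cause over the probe sets that BTH changed in Col-0 it is argued against by slopes of 0.05 and 0.07 in these fits. A response as large as in the single mutants hidden by the spread is argued against, since the slope on the Col-0 changes reached at most 0.16 when 1 array was left out, while it was 0.80 in mkk1 and 1.01 in mkk2. Genes already at their BTH level before treatment as the whole cause is argued against by 212 probe sets that BTH changed in Col-0 and that were not called in untreated mkk1/mkk2, where the mkk1/mkk2 slope was 0.18 (0.03 to 0.37 when 1 array was left out), against 0.72 in mkk1 and 0.87 in mkk2, although untreated mkk1/mkk2 already lay 0.28 of the Col-0 change along that path on these probe sets. As part of the cause it stays open, since 671 of the 1034 risers (64.9%) stood at or above their Col-0 BTH mean in untreated mkk1/mkk2 and 786 of the 972 fallers (80.9%) at or below it, as does a weaker response without both kinases, a hypothesis from these data.

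The 25S ribosomal RNA control, which the comparisons do not use, was at 13.12 on untreated mkk1/mkk2 replicate A, against at most 11.82 in untreated Col-0 and at most 12.27 on any other array. The same array stood apart from its group, and 3 technical explanations were weighed. Less labelled plant RNA is consistent with its mean spike-in control level, 10.05 against at most 9.72 elsewhere, an excess of 0.33. RNA of lower integrity cannot be told apart from the usual spread, since its GAPDH 3' minus 5' difference of 1.27 exceeded the next highest by 0.09, with a within-group SD of 0.23. For RNA of roots or pollen, its root and root hair markers averaged 4.67 (4.43 and 4.55 on the other 2 arrays) and its pollen markers 4.86 (4.68 and 4.82), an excess of at most 0.12. The root list averaged 3.96 in untreated Col-0, under the lower quartile of those arrays (4.02 to 4.05). A list mean near background cannot exclude root RNA, and RNA of pollen is argued against by its marker list alone. No biological explanation was tested.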

How the results depend on the processing

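Chosen after seeing the data were the gene-by-gene array weights, the fit without the 3 arrays that stood apart, the replicate block in the 6-array mkk1/mkk2 fit, the left-out arrays for the likeness and the gene lists, and the split of the untreated Col-0 arrays for the likeness, while the other alternatives were planned. Of 635 named-gene values with a call, none changed direction under the 9 alternatives other than leaving out single arrays. With only the groups compared, the replicate block, no dim probe sets, a variance trend or single-gene probe sets the log2 changes stay as they were. Direction could not turn in these. The call was kept by 476 with only the arrays of the groups compared (159 lost it), 627 with the replicate block, 562 of 571 without the dim probe sets, 606 with median centring, 613 with quantile normalization, 618 with a variance trend, 623 with weights, 617 with single-gene probe sets and 593 without the 3 arrays. Of 87 list shifts, 5 kept their call with an estimated correlation (the count then was 5), 56 with fry, 84 with the replicate block, 83 with median centring and 65 without the dim probe sets, and none turned. Without 1 array 77 to 94 lists shifted, 1950 list values kept their call and 137 lost it, and the chloroplast-encoded polymerase and ribosome list turned for BTH in mkk1/mkk2 without untreated mkk1/mkk2 replicate A (adjusted p = 0.43, and 0.00016 without replicate B). With the replicate block (paired letters) the difference in response for mkk2 fell to 0 and the lists lost were chloroplast-encoded photosynthesis for BTH in mkk1/mkk2 (adjusted p = 0.064) and cold and dehydration proteins and expansins in mkk1/mkk2 at 24 h (0.054 each). Except where fewer arrays or probe sets were used by construction, the cause of each shift below was not tested.

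With gene-by-gene weights the counts were 7769 (BTH in Col-0), 4349 (BTH in mkk1), 5248 (BTH in mkk2), 7721 (untreated mkk1), 4542 (untreated mkk2), 4111, 5989 and 9417 (mkk1, mkk2 and mkk1/mkk2 at 24 h), 1539, 382 and 1710 (differences in response), and the mkk1 slope was 0.69. Weights ran from 0.08 to 4.75. In untreated Col-0 replicates A, B and C had 0.60, 3.66 and 0.78, and after BTH 0.38, 4.75 and 0.64. The weighted Col-0 comparisons thus rest mostly on replicate B. The default estimate, which did not converge, gave BTH-treated Col-0 replicate B a weight of 0.00. Without the 3 arrays they were 3693, 4158, 4250 and 115 for BTH in Col-0, mkk1, mkk2 and mkk1/mkk2, 6643 and 2810 for untreated mkk1 and mkk2, 302 and 703 for these at 24 h, and 5, 0 and 1083 for the differences in response. With only the arrays of the groups compared they were 3747 (BTH in mkk1), 0 (BTH in mkk1/mkk2), 0 and 4183 (untreated mkk2 and mkk1/mkk2), 16 (mkk1 at 24 h), and 2 and 258 (differences in response of mkk2 and mkk1/mkk2). The replicate block in the 6-array mkk1/mkk2 fit gave 0.

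Single-gene probe sets alone, fewer by construction, gave 1052, 972, 1259 and 32 for BTH, 2045, 844 and 3996 untreated, 54, 218 and 2517 at 24 h, 0 and 286 for the differences in response of mkk2 and mkk1/mkk2, and 3148 for the departure from the sum. A 2-fold minimum gave 861, 931, 1141 and 39 for BTH, 1571, 652 and 3878 untreated, and 58, 190 and 2243 at 24 h. Without the 40% dimmest probe sets BTH in mkk1/mkk2 gave 19 and the difference in response of mkk2 3. Median centring gave 37 for BTH in mkk1/mkk2 and 1 for the difference in response of mkk1, quantile normalization 1 for the latter, and a variance trend 1 for the latter and 78 for mkk1 at 24 h. The likeness of untreated mkk1/mkk2 and BTH was 0.42 and 0.66 with the BTH responses of mkk1 and mkk2 in place of Col-0. With the untreated Col-0 arrays split between the comparisons it was 0.63, 0.70 and 0.64 with A, B or C alone for mkk1/mkk2 and 0.63, 0.69 and 0.56 with A, B or C alone for BTH.

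Leaving out 1 array gave 1241 to 3158 for BTH in Col-0, 897 to 3120 in mkk1, 1600 to 3578 in mkk2 and 31 to 181 in mkk1/mkk2. It gave 1745 to 5626 for untreated mkk1 and 341 to 3345 for untreated mkk2, 8 to 1215 and 70 to 1470 for these at 24 h, and 0 to 28, 0 to 26 and 345 to 889 for the differences in response. For mkk1 at 24 h the arrays that moved the count were, in Col-0 untreated A (274) and B (43) and BTH A (8), B (17) and C (863), in mkk1 untreated B (89) and C (50) and BTH A (20), B (15) and C (12), in mkk2 BTH A (41) and B (51), and in mkk1/mkk2 untreated A (1215) and BTH A (80), B (41) and C (47). Counts that stayed within 1.5 times in each left-out run were untreated mkk1/mkk2 (6351 to 8208), mkk1/mkk2 at 24 h (3770 to 6351) and the departure from the sum (5034 to 7962). Signal near background limits small changes. With 3 arrays per group, and equal spread assumed in all groups, the test found 37.31% of simulated differences in response of 1 for mkk1/mkk2.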

Other observations

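The tests of shared Col-0 arrays, of the array sets and of their share of the change were chosen after the results were seen, while the regroupings of arrays were planned, and the genes of the next paragraph were set side by side after their values were seen.

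On some arrays a few genes stood high together, which was not tested. GH9B13, an endoglucanase, stood at 4.95 to 5.38 in untreated Col-0 and 8.40 to 9.60 in untreated mkk1, and at 10.20 on untreated mkk2 replicate B against 5.10 and 5.76 on replicates A and C. PYK10 stood at 4.23 to 5.02 in untreated Col-0, 7.30 to 8.37 in untreated mkk1, 8.52 on untreated mkk2 replicate B against 4.59 and 4.67, and 7.24 on BTH-treated Col-0 replicate A against 5.16 and 3.53. AT1G62500 was at 4.03 to 4.21 in untreated Col-0, 7.88 to 8.56 in untreated mkk1 and 9.63 on untreated mkk2 replicate B against 4.16 and 4.39. The 17 genes of mitosis and histones averaged 6.47 on that mkk2 array against 5.63 and 5.53, and 6.43 on BTH-treated Col-0 replicate A against 5.92 and 5.51. After BTH the 3 mkk1 arrays had GH9B13 at 5.12 to 5.68 and mitosis and histones at 5.62 to 5.90. The mkk1/mkk2 arrays did not follow, with PYK10 at 7.76 to 9.68 untreated and 9.07 to 9.71 after BTH but mitosis and histones at 5.82 to 6.01 and 5.61 to 5.85.

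Untreated mkk1 and mkk2 differed from untreated Col-0 in much the same way. Sharing of the Col-0 arrays as the whole source is argued against, since the covariance of both sets of changes was 8.38 times that of unchanged groups against the same arrays. A processing difference between the array sets cannot be told apart from the genotypes, since bioC minus bioD parted the 12 mkk1 and mkk2 arrays from the other 12 by a gap of 1.11 and no group had arrays in both. Of the 1573 probe sets changed one way in both single mutants, 80.4% (76.3 to 83.4 when 1 array was left out) lay that way in mkk1/mkk2 against Col-0 24 h after BTH, a comparison within 1 array set, with 676 called that way and 73 the other. The bound of 60% set for excluding the array sets as the whole cause was wrong, because no group shows whether a processing difference happens to run in the direction of the double mutant, so this cannot be told apart either, and a shared effect of losing either kinase stays open as a hypothesis.

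For the comparisons of 3 arrays with 3, the 10 splits of the 6 arrays are too few for a share under 0.05. In each of them 1 of 10 splits, the real one, gave as many called probe sets in a fit of the other 18 arrays' groups and the split. The real counts and the highest of the other splits were 2006 and 348 for BTH in Col-0, 1950 and 0 in mkk1, 2444 and 6 in mkk2 and 76 and 4 in mkk1/mkk2. They were 3931 and 2 for untreated mkk1, 1736 and 0 for mkk2 and 7573 and 257 for mkk1/mkk2, and 141 and 0, 417 and 1, and 4918 and 0 for these at 24 h. For BTH in mkk1/mkk2, 4 splits part all 3 pairs of replicate letters, and the highest other among them gave 1, while the rest gave at most 4. For the departure of untreated mkk1/mkk2 from the sum of the single mutants, 1 of 100 regroupings of the 12 arrays, the real one, gave as many as 6094, with at most 4873 in another. The real grouping parts the arrays as the array sets do, and regrouped arrays still carry the differences between the groups. The regroupings therefore cannot tell a departure from a difference between the array sets.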
